A study of Arabidopsis thaliana with 4 samples.

How the data were processed

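Total RNA from roots of wild type and wrky47-1 was hybridised to 4 arrays, 1 for each combination of genotype (wild type, wrky47) and solution (control, Al), and samples were grouped by the genotype and solution in their labels. The design thus has 2 factors and no replicate, and 5 comparisons follow from it: Al against control in each genotype, wrky47 against wild type in each solution, and the difference of the Al responses.

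The authors deposited a table of 22810 probe sets with Affymetrix-style identifiers, each paired with gene codes, gene titles and gene ontology terms. Its normalized columns hold log2 signals, per the file headers and the values, between 3.35 and 14.16. The labels name Cy3 as the dye and the submitters' processing notes name MAS5, without a version or settings. The background correction, the scaling between arrays and the annotation's genome build are not given in the sources used here. The deposited columns headed raw hold intensity values on a linear scale that equal 2 to the power of the normalized column (largest gap on the log2 scale 1.6e-06), so they are summarised and scaled signals, not the scanner's. The authors' values in the second table, named by sample, were identical to the normalized columns probe set by probe set (0 differed), which tied each column to its sample. The tables hold no detection calls, so a signal floor was set from each array. A spread between arrays that was left by the authors' scaling stays in every difference.

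The 64 control probe sets were used only for spike-in and RNA quality values. Of the other 22746 probe sets 20550 name 1 gene, 987 name several genes and 1209 name none. Only the first kind was used for genes, which gave 20341 genes, 205 of them with more than 1 probe set. Such a gene took the probe set with the highest mean over the 4 arrays. Gene codes were matched to a RefSeq gene table of assembly TAIR10.1, used for symbols alone: 20277 matched and 8927 had a symbol. Names follow that table and the gene lists, and a code without a symbol was kept as it is.

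A gene was detected on an array if its signal was above the 40th percentile of the gene probe sets of that array, and measured in a comparison if detected on both arrays, or on all 4 for the difference of the responses. The log2 difference between the arrays was the measure, and genes with a difference of at least 1 (2-fold) in either direction were counted. A gene detected on 1 of the arrays only was given as a bound, the brighter signal over the floor of the other array, as "at least N-fold". The number of arrays limits the precision, and no test across genes was used in place of replicates.

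Gene lists, 30 in number, were fixed by gene code: aluminium tolerance, the XTH family, expansins, extensins and proline-rich wall proteins, pectin methylesterases, cellulose synthesis of the primary wall and of the secondary wall, root hair, Casparian strip and suberin, phenylpropanoid, glucosinolate, jasmonate, ethylene, auxin, abscisic acid and dehydration, salicylic acid and defence, rapid stress and touch, glutathione S-transferases, antioxidant enzymes, heat shock, phosphate starvation, iron deficiency, nitrate response, aquaporins, cell division, DNA damage, the WRKY family, photosynthesis as a marker of green tissue, the circadian clock as a marker of harvest time, and reference genes. Some genes belong to more than 1 list: XTH22, WRKY18, WRKY33, WRKY40 and WRKY53 are also rapid stress genes, WRKY38 and WRKY70 also defence genes, WRKY46 also an aluminium tolerance gene, WRKY75 also a phosphate starvation gene, and XTH26, EXPA7, EXPA18, PRP1, PRP3, EXT12, LRX1 and LRX2 also root hair genes. The median difference of the measured members of a list was placed among the medians of 10000 random lists of the same size, drawn with seed 1 from 20 bins of mean signal, and a list was said to stand apart below the 2.5th or above the 97.5th percentile. This percentile describes these arrays and is no test of the conditions.

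The genes named singly follow a rule: in each comparison the 12 highest and 12 lowest differences among measured genes with a symbol, WRKY47 and XTH17 throughout, for each list described up to 4 members of largest absolute difference among those measured, and up to 4 bounds in each direction. Of the genes this rule names, 1 is not reported here. The groups, comparisons, filter, threshold, lists, naming rule and 10 alternatives were fixed before the data were examined. The alternatives were quantile normalization, centring each array on the median of its detected genes, scaling to the 75th percentile of the signal, no detection filter, a stricter filter at the 60th percentile, thresholds of 1.5-fold and 3-fold, the mean of all probe sets of a gene, an offset of the 20th percentile of the signal added before log2, and the second table. Under the alternatives 2000 random lists were drawn per list.

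The computation was tested on simulated data for Al against control in wild type over 20341 genes. Of 50 genes each changed by 1.5, -1.5, 3.0 and -3.0 on the log2 scale, 50, 49, 50 and 50 passed 2-fold in the right direction, and 0 of 12474 unchanged genes did. All changed genes were bright ones, well above the detection floor, and their recovery was counted without the detection filter. The noise was normal with the same SD at every signal and no shift between arrays. The simulation thus checks the arithmetic and gives no error rate for dim genes or for real single arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used. No column of values was left out for want of a sample.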

Results

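Transcript levels were measured in roots of 4-week-old Arabidopsis thaliana plants of 2 genotypes, the wild type and the mutant wrky47-1, which is disrupted in the gene of the transcription factor WRKY47. Plants from hydroponic culture spent 6 h in 0.5 mM CaCl2 without aluminium (control solution) or with 25 µM AlCl3, which gives 4 groups with 1 array each. With n = 1 per group no difference could be set against a spread between replicates. No p-value was computed, and every difference is one between single arrays without a replicate check. The median log2 signal of the gene probe sets was 7.20 in wild-type control, 7.15 in wrky47 control, 7.06 in wild-type Al and 7.10 in wrky47 Al. The detection floor, the 40th percentile of each array, lay at a linear signal of 81.1, 79.1, 75 and 75.1 in the same order, and between 12838 and 12855 of the 20341 genes were above it on an array. The Dap spike-in, a bacterial transcript added during preparation, had a mean log2 signal of 7.74 on the wild-type control array and 8.25, 8.21 and 8.22 on the wrky47 control, wild-type Al and wrky47 Al arrays.

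The targeted gene was measured first. WRKY47 (AT4G01720) had a signal of 172.9 in wild-type control and 203.4 in wild-type Al, a log2 difference of 0.23. In wrky47 its signals of 27.5 in control and 24.1 in Al were below the floor, so that it was at least 2.19-fold lower than in wild type in control solution and at least 2.71-fold lower in Al. Where the mutation lies relative to the probe set is not given in the sources used here. XTH17 (AT1G65310), a xyloglucan endotransglucosylase/hydrolase that remodels the xyloglucan of the cell wall, had signals of 129.8 in wild-type control, 63.1 in wrky47 control, 554.5 in wild-type Al and 343.0 in wrky47 Al. It rose with Al by 4.27-fold (2.1 on the log2 scale) in wild type and by at least 4.34-fold in wrky47. In wrky47 it was at least 1.64-fold lower than in wild type in control solution, where the mutant signal was below the floor, and its log2 difference was -0.69 in Al.

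The first comparison asked what 6 h of Al did to wild-type roots. Among genes with a symbol detected in both solutions, PLA2A, a patatin-like lipid hydrolase of wounding and defence, had the highest log2 difference (4.00), followed by the wall enzyme XTH23 (3.43), the dark-inducible asparagine synthetase ASN1 (3.19), the blue copper-binding protein BCB (3.13) and the glutathione transferases GSTU4 (3.0) and GSTU11 (2.96). TAT3 (2.86), a tyrosine aminotransferase, the transporter ABCG16 (2.84), NANA (2.66), YLS9 (2.58), the arabinogalactan protein AGP2 (2.55) and ACS7 (2.54), which makes the ethylene precursor, completed the 12 highest. CASP1, a scaffold protein of the endodermal Casparian strip, had the lowest value of these genes and fell by 3.41 from a signal of 2649 to 250. The strip dirigent protein ESB1 (-2.29) and the strip peroxidase PER64 (-2.21) fell as well. So did the ubiquitin ligase ATL15 (-2.80), the root sulfate transporter SULTR1;2 (-2.75), the nicotianamine synthase NAS1 (-2.63), the phosphoenolpyruvate carboxylase PPC3 (-2.53), the tonoplast aquaporin TIP4;1 (-2.30), G6PD3 (-2.26), AZI1 (-2.19), GLIP2 (-2.00) and FLS5 (-1.99). Among genes detected in 1 solution only, the caffeoyl-CoA methyltransferase CCOAMT was at least 18.23-fold higher in Al, UGT74E2 at least 6.99-fold, NAC3 at least 5.90-fold and GAT1_2.1 at least 5.26-fold. FAH1, the ferulate hydroxylase of lignin synthesis, was at least 6.97-fold lower, RHS13 at least 6.07-fold, the iron transporter IRT1 at least 5.33-fold and CASP2 at least 5.28-fold.

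Of 12434 genes measured in both solutions in wild type, 379 rose and 301 fell by 2-fold or more, and a further 68 and 52 were at least 2-fold higher or lower as bounds. The median of all measured genes was -0.12 on the log2 scale, and relative to it 488 genes were higher and 211 lower by 2-fold. Of the 30 gene lists, 12 had a median that stood apart above random lists of like signal and 5 below. For 30 independent lists 0.75 would be expected on each side.

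Stress-signalling lists moved upward in wild type. Of 13 measured rapid stress and touch genes 9 rose, with MYB15 at 1.98, ZAT10 at 1.64 and TCH3 at 1.46. The list median of 1.21 was above all 10000 random lists. Among 15 glutathione S-transferases 6 rose, with GSTU12 at 2.18 and GSTU25 at 2.13. The median of 0.55 was above all random lists. Ethylene genes had 6 of 15 members that rose, among them the response factors ERF6 (2.12), ERF2 (1.89) and ERF5 (1.24). Their median of 0.50 was also above all random lists. In the WRKY family 6 of 22 rose and 1 fell, with WRKY45 at 2.31, WRKY75 at 2.07, WRKY33 at 1.44 and WRKY70 at 1.37. The median of 0.49 was above all random lists. Jasmonate genes rose in 4 of 12 cases (JAZ5 1.49, JAZ10 1.11, JAZ6 1.03, AOC3 1.02), with a median of 0.41 (percentile 99.94). Salicylic acid and defence genes rose in 3 of 10 cases, namely PAD3 and CYP71A12 of camalexin synthesis (1.69 and 1.43) and WRKY70. The median was 0.54 (percentile 99.97). Auxin genes had 3 members that rose and 2 that fell out of 15, with the auxin-conjugating GH3.1 at 1.71, GH3.5 at 1.47 and GH3.3 at 1.34 against the auxin synthesis gene YUC3 at -1.18. Their median was 0.13 (percentile 99.64). No member of the 9 measured abscisic acid and dehydration genes passed 2-fold, while their median of 0.35 lay at percentile 99.67.

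Aluminium tolerance genes had a median of 0.39 (percentile 99.98), with 2 of 17 risen and 1 fallen. The citrate exporter MATE was at 1.01 and PGIP1 at 1.27, the potassium transporter HAK5 at -1.32, and the malate channel ALMT1, which did not pass 2-fold, at 0.85. In the XTH family 7 of 19 rose and 2 fell, with XTH18 at 2.46 and XTH22 at 2.36 after XTH23, and the median was 0.56 (percentile 99.99). That list was fixed with knowledge of the published account of this mutant and is not independent evidence of its direction, in any of the comparisons. The Casparian strip and suberin list divided, as 3 of 16 rose and 3 fell. The 3 that fell were CASP1, ESB1 and PER64, while CYP86B1 of suberin monomer synthesis rose by 1.24. The list median of 0.68 was above all random lists, but 12 of the 16 measured members were suberin genes. Strip genes below the floor in Al, such as CASP2, entered neither this count nor the median. With bounds included, 5 of the 7 strip genes detected in control solution lay below -1.04. Phenylpropanoid genes had 1 of 14 risen, CCR2 at 1.22, with PAL2 at 0.88 and CAD4 at -0.84, and a median of 0.20 (percentile 98.77). FAH1 of this list, lower as a bound, entered neither this count nor the median.

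Nitrate response genes fell together in wild type, 8 of 11 by 2-fold or more, with G6PD3, UPM1 (-1.93), the nitrite reductase NIR1 (-1.79) and FNR2 (-1.67). Their median of -1.39 was below all random lists. All 11 measured cell division genes were below 0. CYCB1;4 (-1.04), CDKB2;1 (-1.04) and KNOLLE (-1.02) were just beyond 2-fold as deposited, and 0 of the 11 passed it after quantile normalization, centring or scaling to the 75th percentile. The median was -0.84 (-0.73 after quantile normalization), in both cases below all random lists. Aquaporins had 4 of 15 fallen (2 after centring or scaling to the 75th percentile), among them TIP4;1 and TIP2;3 (-1.32), and 1 risen, PIP2;6 (1.15). Their median was -0.51, below all random lists. Expansins were below 0 in 9 of 10 cases and 1 of them fell, EXPA14 by 1.04, with a median of -0.56, below all random lists. Of 5 measured root hair genes none passed 2-fold and 2 more were lower as bounds. ADF8 was at -0.99, PRX73 at -0.91 and PRX44 at -0.71, and the list median was -0.71 (percentile 0.12).

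Other lists lay among the random lists in wild type. Their medians were 0.05 for extensins (7 measured, EXT1 risen by 1.56, percentile 81.9), -0.15 for pectin methylesterases (8 measured, PME17 at 1.84 and PME1 at 1.08, percentile 37.54), 0.14 for primary-wall cellulose synthesis (9 measured, percentile 92.4) and -0.16 for secondary-wall cellulose synthesis (12 measured, percentile 36.95). Glucosinolate genes had a median of -0.19 (10 measured, MYB51 risen by 1.53, MYB34 at -1.18, percentile 22.25), antioxidant enzymes -0.26 (11 measured, CAT2 at -1.06, percentile 5.94), heat shock genes -0.16 (7 measured, percentile 42.94) and phosphate starvation genes -0.19 (9 measured, WRKY75 risen, percentile 33.47). Iron deficiency genes stood at 0.05 (10 measured, NAS1 and NAS2 fallen, the latter by 1.39, percentile 93.2), DNA damage genes at -0.15 (4 measured, percentile 44.74), photosynthesis genes as a marker of green tissue at -0.02 (4 measured, percentile 81.26), clock genes as a marker of harvest time at -0.24 (6 measured, percentile 18.57) and reference genes at -0.02 (10 measured, percentile 69.01). The mean had the opposite sign to the median for pectin methylesterases (0.18), phosphate starvation (0.05), iron deficiency (-0.40), photosynthesis (0.17) and reference genes (0.01). Without the detection filter the medians of the XTH family (0.04) and the phenylpropanoid genes (0.09, percentile 94.8) did not stand apart. The same held for the salicylic acid and defence genes (0.04, 84.45). With the stricter filter that of the abscisic acid genes (0.16, 93.65) did not stand apart. The photosynthesis genes stood apart above the random lists without the filter (0.31 over 11 genes, percentile 99.8).

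In wrky47 roots the 12 highest of the genes with a symbol detected in both solutions were TAT3 (4.64), PLA2A (3.78), ASN1 (3.58), XTH23 (3.49), CCOAMT (3.44), BCB (3.11), XTH18 (3.06), ACS7 (2.98), the glycosyltransferase UGT74E2 (2.88), GSTU4 (2.70), WRKY75 (2.63) and CYP81D8 (2.62). The 12 lowest of these genes were ATL15 (-3.23), SULTR1;2 (-3.02), the cytochrome P450 CYP712A1 (-2.88), the amino acid exporter UMAMIT14 (-2.82), CASP1 (-2.73), AZI1 (-2.71), PPC3 (-2.69), NAS1 (-2.43), the metal transporter ZIP2 (-2.39), FLS5 (-2.29), a bZIP factor (-2.26) and PER64 (-2.15). As bounds, MAPKKK19 was at least 6.28-fold higher, sks9 at least 4.44-fold and LOG5 at least 4.27-fold, while FAH1 was at least 6.95-fold lower, RALFL27 at least 4.53-fold and TIP4;1 at least 3.27-fold. Of 12465 measured genes 426 rose and 245 fell, with 71 and 38 more as bounds. Relative to the median of -0.07 the counts were 488 and 203.

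In wrky47, 12 lists were again above and 4 below the random lists. Rapid stress and touch genes rose in 10 of 13 cases, with MYB15 at 2.25 and TCH3 at 1.77 (median 1.43), and the WRKY family in 10 of 22 (median 0.85). Glutathione S-transferases rose in 6 of 14 (median 0.78) and salicylic acid and defence genes in 5 of 11, with CYP71A12 at 2.29 and PAD3 at 2.01 (median 0.79). Each of these medians was above all random lists, as were those of the aluminium tolerance genes (0.55, with 2 of 17 risen and 2 fallen), the XTH family (0.39, 7 of 18 risen) and the Casparian strip and suberin genes (0.65, 3 of 17 risen and 3 fallen). In the last list 13 of the 17 were suberin genes. With bounds included, 5 of the 6 strip genes detected in control solution lay below -1.32. Ethylene genes rose in 6 of 14 cases (median 0.48, percentile 99.99), auxin genes in 4 of 14 (0.34, percentile 99.92), jasmonate genes in 4 of 12 (0.33, percentile 99.58) and abscisic acid genes in 0 of 9 (0.42, percentile 99.79). Photosynthesis genes had 1 of 3 risen, LHCA4 at 1.05, with a median of 0.43 (percentile 98.22). Nitrate response genes fell in 9 of 11 cases, with NRT2.1 at -1.69 and NIR1 at -1.65 (median -1.47), aquaporins in 4 of 14, with PIP1;5 at -1.44 (median -0.42), and cell division genes in 3 of 11, with CYCB1;4 at -1.32 (median -0.87), all 3 medians below all random lists. Secondary-wall cellulose genes were below 0 in 10 of 11 cases, none by 2-fold, with CESA4 at -0.64, and their median was -0.33 (percentile 0.94). The medians of the auxin genes (0.06, percentile 95.25) without the filter, of the jasmonate genes (0.10, percentile 84.4) with the stricter filter and of the photosynthesis genes (percentile 97.45) after quantile normalization did not stand apart.

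The responses of the genotypes to Al were then set against each other, from arrays that they did not share. Across the 12223 genes detected on all 4 arrays the log2 responses had a Pearson r of 0.879 and a Spearman rho of 0.781, computed across genes, which are not independent replicates. Of the 372 genes of this set that rose in wild type and the 403 that rose in wrky47, 300 were shared, against 12.3 for independent lists. Of the 282 and 240 that fell, 170 were shared, against 5.54, and no gene passed 2-fold in opposite directions.

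**Figure D1:**
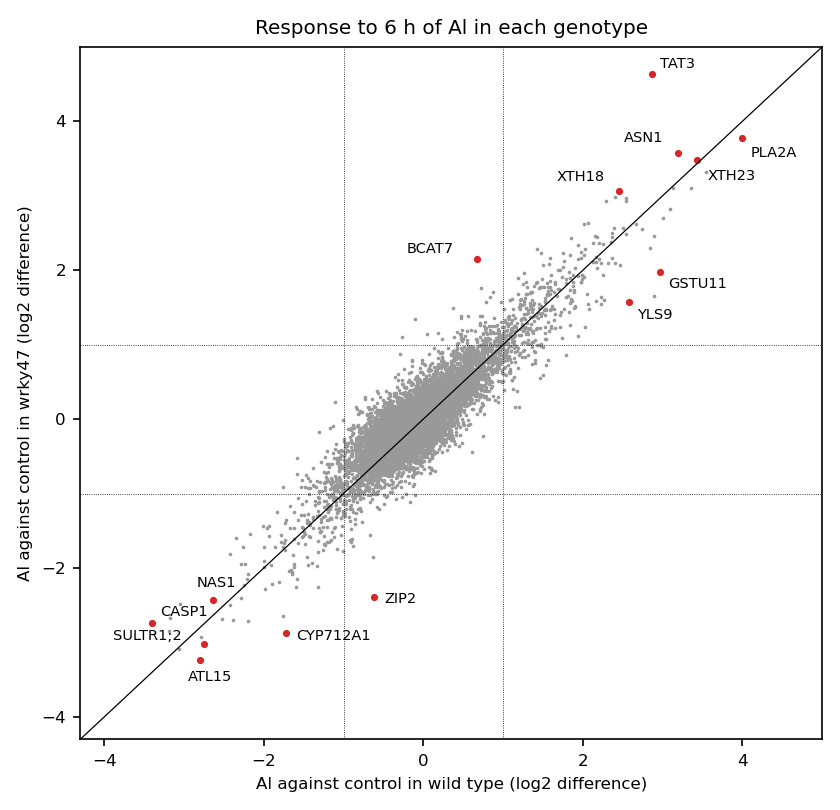
Log2 difference of Al against control in wrky47 (vertical axis) against that in wild type (horizontal axis), each point 1 of the 12223 genes detected on all 4 arrays, with dotted lines at 2-fold, a diagonal line of equal responses and named genes in red. PLA2A (4.00 and 3.78) and XTH23 (3.43 and 3.49) lie near the diagonal, TAT3 (2.86 and 4.64) above it and ZIP2 below it.

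The genotypes were next compared in control solution. Among genes with a symbol detected in both genotypes, the iron transporter IRT1 had the lowest difference in wrky47 (log2 -2.33), followed by the extensin-like ELP (-1.94), the root hair gene RHS13 (-1.45), AGL79 (-1.36), the actin-depolymerizing factor ADF11 (-1.20), SDR5 (-1.17), the branched-chain aminotransferase BCAT7 (-1.16), SCPL11 (-1.15), TAT3 (-1.14), ARP1 (-1.14), the stelar potassium channel SKOR (-1.08) and the peroxisome protein PEX11E (-1.08). UMAMIT14 had the highest of these differences (1.84), followed by scpl30 (1.29), CWLP (1.07), CBL8 (1.07), the sulfate transporter SULTR2;1 (1.03), FMO GS-OX3 (1.00) and the iron superoxide dismutase FSD1 (1.00). Under 2-fold came CEP1 (0.98), THAS1 (0.96), GSTU6 (0.92), ZIP2 (0.91) and NYC1 (0.90). As bounds, BARS1 was at least 2.40-fold and the root hair gene ADF8 at least 2.28-fold lower in wrky47.

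Of 12602 genes measured, 13 were higher and 26 lower in wrky47 by 2-fold, with 0 and 4 more as bounds. The share of higher genes was 33.3% as deposited and 50% after quantile normalization (19 higher, 19 lower), 48.7% after centring each array (18 and 19) and 51.4% after scaling to the 75th percentile (19 and 18). Relative to the median of -0.05 the counts were 18 and 19.

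Root hair genes and 3 of the 6 wall lists stood apart below the random lists in wrky47 in control solution. No measured member of these 4 lists passed 2-fold, and the root hair gene ADF8 did as a bound. All but 1 of the 6 measured root hair genes were below 0, with PRP3 at -0.81, PRX44 at -0.78, EXPA7 at -0.76 and PRX73 at -0.60. The median of -0.68 was below all random lists. The XTH family was below 0 in 13 of 18 cases, with XTH14 at -0.95, XTH18 at -0.82, XTH4 at -0.68 and XTH8 at -0.51. Its median of -0.30 was below all random lists. Secondary-wall cellulose genes, 10 of 11 below 0 with CESA7 at -0.61, had a median of -0.32 (percentile 0.06). Expansins, 11 of 13 below 0 with EXPB1 at -0.70, had a median of -0.26 (percentile 0.23). The other wall lists lay among the random lists, with medians of -0.19 for extensins (7 of 8 below 0, percentile 4.32), -0.13 for pectin methylesterases (6 of 9 below 0, percentile 14.63) and -0.02 for primary-wall cellulose synthesis (6 of 9 below 0, percentile 68.94). Glutathione S-transferases had 9 of 14 members above 0, with GSTU4 at 0.80 and GSTU25 at 0.72 (median 0.07, percentile 98.49). DNA damage genes had 3 of 4, with WEE1 at 0.55 (median 0.30, percentile 99.62). In the Casparian strip and suberin list CASP2 (-1.06) and CASP1 (-1.04) were lower, while the median of its 18 measured members, -0.06, lay at percentile 46.15. Photosynthesis genes, the marker of green tissue, were below 0 in 3 of 3 cases, with LHCA4 at -0.83 and LHCB4.1 at -0.78 (median -0.78, percentile 0.02). The Dap spike-in, whose range over the 4 arrays was 0.51, was lowest on the wild-type control array of this comparison. Without the detection filter the medians of the expansins (-0.06, percentile 20.85), glutathione S-transferases (0.05, 94.4), DNA damage genes (0.07, 78.7) and photosynthesis genes (-0.12, 6.95) did not stand apart. Those of the pectin methylesterases (-0.20, 0.6), iron deficiency (-0.18, 0.05), jasmonate (0.11, 99.4) and ethylene genes (0.07, 98.0) then did. With the stricter filter those of the expansins (-0.15, 17.22) and glutathione S-transferases (percentile 96.45) did not stand apart, while those of the ethylene genes (0.12, 99.8) and aquaporins (-0.17, 0.6) did. The ethylene genes also stood apart with the mean of probe sets (0.06, 97.8).

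In Al the lowest differences among genes with a symbol detected in both genotypes were those of CYP712A1 (-1.56), the arabinogalactan proteins FLA13 (-1.42) and AGP7 (-1.06), ATCTH (-1.25), TSBtype2 (-1.11) and TPS8 (-1.11). Just under 2-fold were PEX11E (-1.0) and, further from it, the metal transporters ZIP9 (-0.99) and ZIP2 (-0.86), the sulfate transporter SULTR1;1 (-0.94), GASA1 (-0.92) and the root hair peroxidase PRX44 (-0.87). The 12 highest of these differences were those of the endoplasmic reticulum chaperone BIP3 (1.5), PYD4 (1.36), the glutamate dehydrogenase GDH3 (1.22), NDB4 (1.22), PIP5K2 (1.18), the expansin-like EXLA3 (1.16), LTP3 (1.09), ATC (1.08), the chlorophyll b reductase NYC1 (1.06), CEP1 (1.05), CRK10 (1.04) and ALD1 (1.04) of pipecolic acid synthesis. ELP was at least 3.67-fold and RALFL27 at least 2.35-fold lower in wrky47, and GolS2 at least 2.195-fold higher.

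Of 12602 genes measured in Al, 29 were higher and 14 lower in wrky47, with 3 and 3 more as bounds. Relative to the median of 0.00 the counts were 29 and 15. All 10 measured salicylic acid and defence genes were above 0 in wrky47, none by 2-fold, with CYP71A12 at 0.92, the salicylic acid synthesis gene ICS1 at 0.79, NIMIN1 at 0.78 and FMO1 at 0.73. The median of 0.48 was above all random lists. In the WRKY family 17 of 23 were above 0 and 1 passed 2-fold, WRKY18 at 1.01, with WRKY75 at 0.76 and WRKY48 at 0.65. The median of 0.22 was above all random lists. Glutathione S-transferases had 11 of 17 members above 0, with GSTU25 at 0.96 (median 0.17, percentile 99.9). Expansins had 7 of 9, with EXPB2 at 0.67 (median 0.25, percentile 99.76), and DNA damage genes 4 of 5, with TSO2 at 0.30 (median 0.26, percentile 98.29).

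Wall lists below the random lists in Al included the extensins, 7 of 7 below 0 with EXT9 at -0.68 and EXT15 at -0.55 (median -0.47). Secondary-wall cellulose synthesis had 10 of 11 below 0 with CESA4 at -0.76, XCP1 at -0.69 and CESA7 at -0.65 (median -0.49). Both medians were below all random lists. The XTH family had 15 of 20 members below 0, with XTH14 at -0.78 (median -0.18, percentile 0.05). Primary-wall cellulose genes were below 0 in 9 of 9 cases, with CESA6 and CTL1 at -0.34 (median -0.17, percentile 2.04), and pectin methylesterases in 5 of 8, with PME1 at -0.54 (median -0.17, percentile 1.28). The Casparian strip and suberin list had 10 of 17 members below 0, with PER64 at -0.78 (median -0.14, percentile 0.65), and aquaporins 10 of 14, with PIP1;5 at -0.71 (median -0.21, percentile 0.03). Photosynthesis genes, the marker of green tissue, were at the limit with 2 of 3 below 0 (median -0.26, percentile 2.49), and root hair genes, 3 of 5 below 0, had a median of -0.06 (percentile 28.28), or -0.18 over 17 genes without the filter, below all random lists. Without the filter the expansin median turned to -0.02 (percentile 40.72), and those of the pectin methylesterases (percentile 5.3) and primary-wall genes (2.7) no longer stood apart. With the stricter filter the same held for the expansins (0.13, percentile 96.45), primary-wall genes (2.55) and Casparian strip and suberin genes (-0.07, 24.85), after quantile normalization for the primary-wall (2.8) and DNA damage genes (97.1), with the offset for the DNA damage (96.15) and photosynthesis genes (2.88), and with the mean of probe sets for the photosynthesis genes (3.6).

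**Figure D2:**
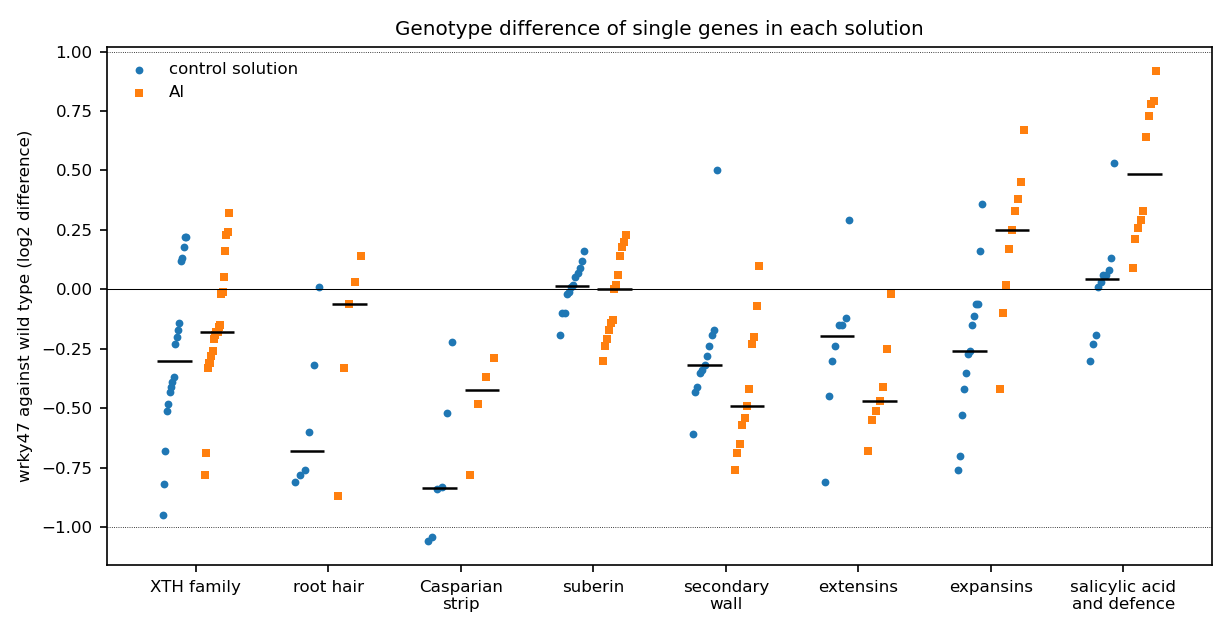
Log2 difference of wrky47 against wild type for the single measured members of 8 groups (Casparian strip and suberin genes parted after their values were seen) in control solution (blue circles) and in Al (orange squares), with a black line at each median and dotted lines at 2-fold. Root hair genes have medians of -0.68 in control solution and -0.06 in Al, and salicylic acid and defence genes 0.04 and 0.48.

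The genotype comparisons share no array with each other, whereas each shares 1 array with each Al comparison, so that the chance error of that array enters both. Across the 12223 genes detected on all 4 arrays the genotype differences in the 2 solutions had a Pearson r of 0.433 and a Spearman rho of 0.371. Of the 16 and 12 genes of this set lower in wrky47 in control solution and in Al, 2 were shared, against 0.02 for independent lists. They were AT3G24100 (-1.02 and -1.08) and the proline-rich extensin-like AT3G28550 (-1.0 and -1.45), both without a symbol and chosen after their values were seen. Of the 9 and 27 higher genes 0 were shared.

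The last comparison was the difference of the Al responses, wrky47 minus wild type. The tyrosine aminotransferase TAT3 (1.77), BCAT7 (1.47), the actin-bundling villin VLN1 (1.04), CYP91A2 (1.03) and the lipid transfer protein LTP3 (1.01) had the more positive response in wrky47. ZIP2 (-1.77), CYP712A1 (-1.16) and YLS9 (-1.01) had the more negative one. Next to them, under 2-fold, stood PME41 (0.98), HMGB6 (0.96), WRKY38 (0.94), TRM12 (0.93), EDA14 (0.92), CIPK13 (0.92) and AGL72 (0.92) on the positive side. On the negative side were the aquaporin PIP2;6 (-0.99), the urea transporter DUR3 (-0.98), GSTU11 (-0.98), ORA59 (-0.95), MYB77 (-0.92), scpl30 (-0.92), MES1 (-0.83), SULTR1;1 (-0.81) and CBL8 (-0.81). For XTH17 and WRKY47 this difference was not measured, as signals in wrky47 were below the floor.

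In this comparison 16 genes had a difference of 2-fold or more upward and 7 downward. The share of upward differences was 69.6% as deposited, 47.6% after quantile normalization (10 and 11), 42.9% after centring (9 and 12) and 42.9% after scaling to the 75th percentile (9 and 12). Relative to the median of 0.05 the counts were 10 and 10. Salicylic acid and defence genes had a more positive response in wrky47 in 10 of 10 cases, with WRKY38 at 0.94 and CYP71A12 at 0.86. Their median of 0.42 was above all random lists. The same sign held for 7 of 9 expansins, with EXPA1 at 0.91 and EXPA6 at 0.71 (median 0.31, percentile 99.76), 16 of 21 WRKY genes (median 0.23, percentile 99.66) and 10 of 14 auxin genes, with IAA14 at 0.68 (median 0.23, percentile 97.68). Secondary-wall cellulose genes had the more negative response in 9 of 11 cases, with CESA4 at -0.48 (median -0.23, percentile 0.02). Primary-wall genes did in 7 of 9, with CESA6 at -0.31 (median -0.20, percentile 0.12), pectin methylesterases in 7 of 8 (median -0.13, percentile 1.95) and glucosinolate genes, at the limit, in 7 of 10 (median -0.10, percentile 2.48). The XTH family did not stand apart (12 of 18 above 0, median 0.09, percentile 84.28), and the same held for the aluminium tolerance genes (9 of 17 below 0, median -0.02, percentile 17.98). The auxin genes did not stand apart with the stricter filter (median -0.04), after quantile normalization (percentile 97.4), with the offset (0.17, percentile 95.8) or with the mean of probe sets (97.45), nor did the pectin methylesterases after quantile normalization (3.75) and without the filter (6.85), or the WRKY family without the filter (0.15, 95.85). The glucosinolate genes did not after quantile normalization (4.2), with the stricter filter (6.52) or with no filter, centring, scaling to the 75th percentile or the second table (each 3.7), the last of which has identical values and differs only in the draw of random lists.

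**Figure D3:**
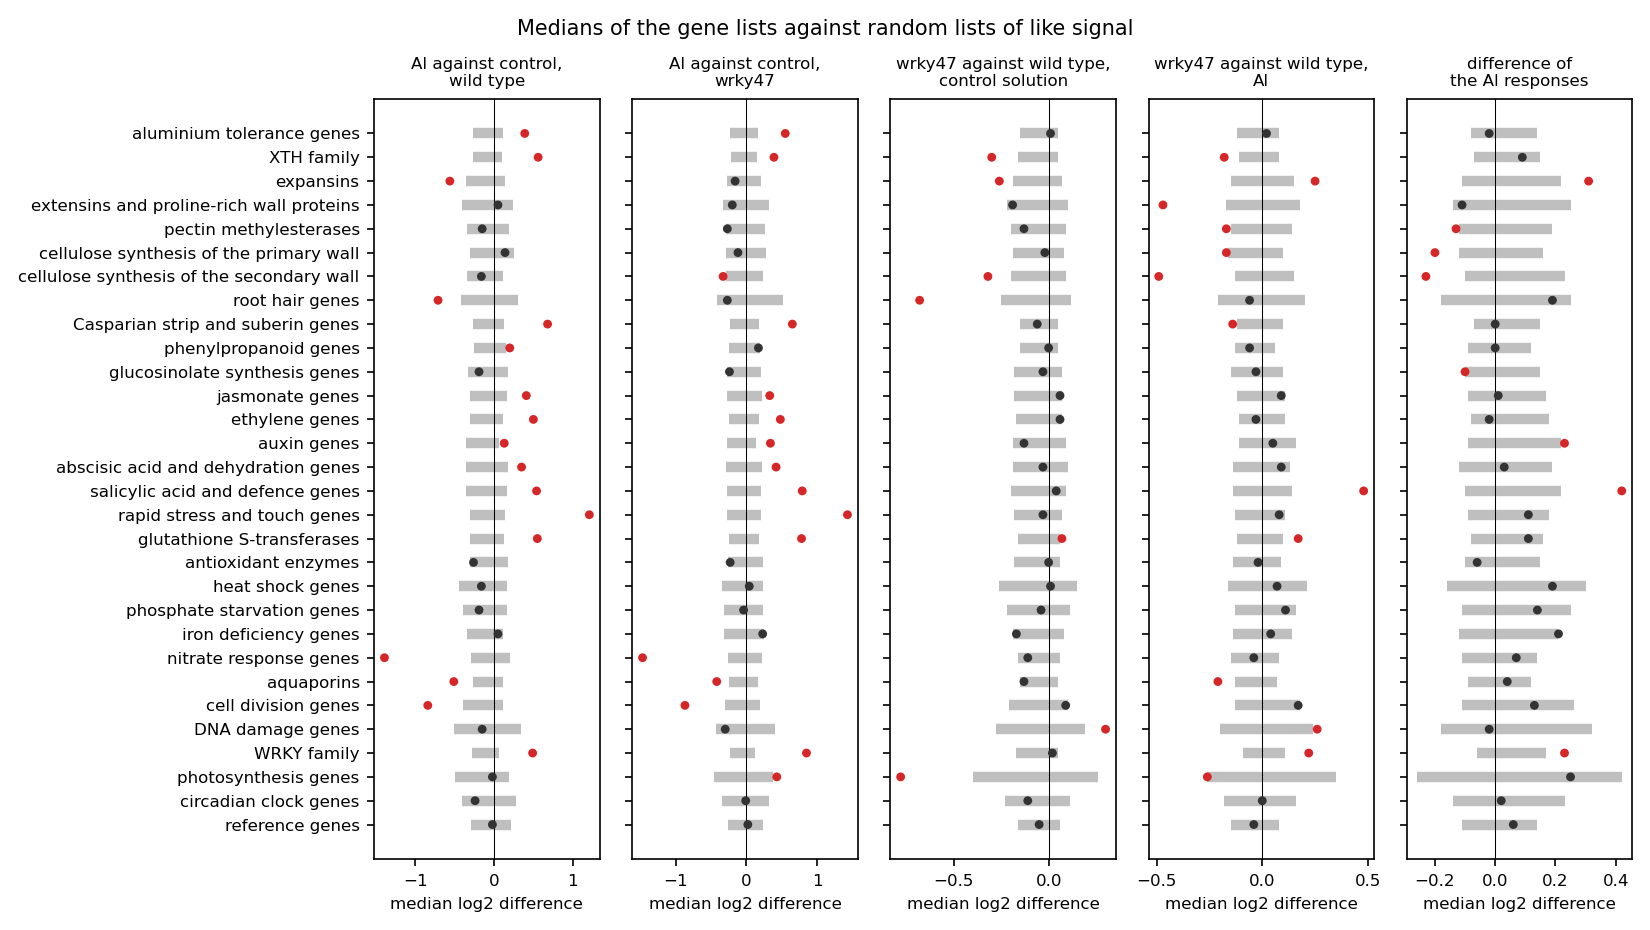
Median log2 difference of each of the 30 gene lists in the 5 comparisons (dots), with the range of random lists between the limits used for standing apart as grey bars and medians outside it in red. Nitrate response genes lie at -1.39 and -1.47 in the Al comparisons, and salicylic acid and defence genes at 0.48 in the genotype comparison in Al.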

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

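The tests of explanations given here were chosen only after the results they bear on were seen. Quantile normalization, however, was among the alternatives fixed in advance. The parting of the Casparian strip genes from the suberin genes was also made after their values were seen. A shift of a whole array moves a list and its random lists alike. The percentile after quantile normalization therefore adds little, and the size of the median is what bears on scaling.

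The root hair genes were lower in wrky47 in control solution, and the trichoblast differentiation term of the deposited annotation, which shares 9 of its 45 members with the list, had 22 of 23 measured members below 0 (median -0.70, below all random lists). Scaling of the arrays is argued against by a list median of -0.62 after quantile normalization, still below all random lists. A wild-type control array that alone stands apart is argued against as the whole cause by the Al arrays, for list and term together. These had a median genotype difference of -0.27 there, with 15 of 17 members below 0, against -0.6 in control solution. The term was picked after its values were seen. The list alone was at -0.06 in Al, among the random lists (-0.18 and below all of them without the filter). A share from that array, which had the lowest mean signal of the Dap spike-in (7.74), thus stays open. What also stays open is less transcript from the differentiation zone on the wrky47 arrays. The Casparian strip genes of the same zone had a median of -0.84 in control solution with 6 of 6 below 0, while the suberin genes were at 0.01 and the cell division genes at 0.09. In Al the strip genes were at -0.42 with 4 of 4 below 0, the suberin genes at 0.0 and the cell division genes at 0.17. An effect of the mutation on root hair genes may also account for the pattern and was not tested apart from such a loss of transcript, with 1 array per group.

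The Casparian strip genes fell with Al while the suberin genes were higher, with medians of -2.25 (4 of 4 measured below 0) and 0.72 (12 of 12 above 0) in wild type and -2.04 (4 of 4) and 0.69 (13 of 13) in wrky47. Scaling of the arrays is argued against by a strip median of -2.17 in wild type after quantile normalization, below all random lists. A smaller share of young root tissue is not excluded, as all 11 measured cell division genes, which mark the youngest tissue, were below 0 in each genotype. Their medians were -0.84 in wild type and -0.87 in wrky47, below all random lists. Such a share alone would not give the size of the strip fall if both kinds of gene lost alike. In wild type 5 of the 7 strip genes detected in control solution fell by more than the cell division gene that fell most (CDKB2;1 at -1.04). In wrky47 5 of 6 did (CYCB1;4 at -1.32). A smaller share of the zone of early differentiation alone is not settled: root hair list and trichoblast term together were at -0.51 in wild type, below all random lists, and -0.23 in wrky47 (percentile 3.18), the list alone at -0.71 and -0.27 (percentile 9.4, but -0.28 over 17 genes and below all random lists without the filter), and the term outside the list at -0.24 and -0.17, both among the random lists. An opposite response of the strip and suberin programmes to Al is a hypothesis that these values may also reflect.

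The salicylic acid and defence genes were higher in wrky47 than in wild type in Al in 10 of 10 cases (median 0.48). The salicylic acid synthesis term of the annotation went the same way by less, with 104 of 162 members above 0. Its median was 0.11, or 0.12 relative to genes of like signal. The Al responses of the term were 0.44 in wild type and 0.46 in wrky47. Scaling of the arrays is argued against by a median of 0.48 after quantile normalization, above all random lists. A response to Al stronger by a like ratio in all Al-responsive genes of wrky47 is argued against by the rapid stress and touch genes. Their median difference of the responses was 0.11, with members from -0.31 to 0.84, where 0.94 would be needed. It was 0.16 (percentile 97.7) without the filter and 0.18 (98.1) with the stricter filter, so a smaller shared rise is not excluded. Across genes the mean Al response and the difference of the responses had an r of 0.002. This r reflects only the like spread of the 2 responses (SD 0.501 and 0.502). It argues against larger rises and falls alike, and cannot exclude larger rises with smaller falls. WRKY38 and WRKY70 belong to the WRKY list too, so the shifts of both lists are not independent. A stronger response of the listed defence genes in the mutant may account for the values and stays a hypothesis from 1 array per group.

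Several results had opposite signs in the genotypes or solutions, and none of these differences was tested. For Al against control, AT1G63530, a hypothetical protein, was at -0.10 in wild type and 1.34 in wrky47, AT2G30670, of the Rossmann-fold family, at -1.11 and 0.23, and AT4G33710, annotated as a pathogenesis-related protein, at -0.26 and 1.11; these 3 have no symbol and were chosen after their values were seen. The values of -0.10 and -0.26 lie within the robust SD of 0.34 of the median of all genes in wild type, -0.12, and that of 0.23 within the robust SD of 0.33 of the median in wrky47, -0.07, so that none of the 3 is read as a change. For wrky47 against wild type, BCAT7 was at -1.16 in control solution and 0.31 in Al, TAT3 at -1.14 and 0.63, and the median of the expansins at -0.26 (13 measured) and 0.25 (9 measured). The expansin median in Al was -0.02 without the filter, and with the stricter filter neither median stood apart (-0.15, percentile 17.22, and 0.13, percentile 96.45). A signal also appeared in probe sets that no comparison of genes used. Of 587 measured probe sets that name several genes 30 were higher and 13 lower by 2-fold in Al in wild type, and of 98 that name no gene 1 was higher and 0 lower.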

How the results depend on the processing

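No alternative was added after the results were seen. The named genes and the list members of largest difference gave 5396 values under 8 alternatives (426 of 710 could be measured with the stricter filter), of which 5330 moved by less than 0.20 on the log2 scale (the robust SD of the genotype difference in control solution), 66 moved by more, all with the offset, and 0 reversed. Much of this was fixed in advance. No filter, the stricter filter and the second table leave a gene's value as it is. Centring and 75th-percentile scaling shift all genes of a comparison alike. The mean of probe sets alters only genes with more than 1 probe set. Quantile normalization and the offset could move single genes by unlike amounts, and they moved 0 and 66 of 710. Neither is free, since quantile normalization keeps the order of the probe sets on an array and the offset shrinks differences. Both were therefore unlikely to reverse a sign. Of 1186 list medians 1067 moved by less than the spread of random lists, 117 moved by more and 2 reversed: the expansins in the genotype comparison in Al were at -0.02 without the filter, and the auxin genes in the difference of the responses at -0.04 with the stricter filter. The cause was not tested. Of 61 list results that stood apart 40 did so on the same side in every alternative. Quantile normalization ended 6 of them, no filter 14, the stricter filter 9 of 56, the offset 3 and the mean of probe sets 2. Centring, 75th-percentile scaling and the second table each ended 1, and since the second table is identical, that 1 shows only the noise of drawing random lists at the limit. Of 89 list results among the random lists 16 stood apart in 1 alternative or more, 13 of them without the filter and 5 of 80 with the stricter filter. Without the filter, over 17 genes, these included the root hair genes for Al in wrky47 (-0.28), for genotype in Al (-0.18) and for the difference of the responses (0.20).

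The stricter filter left fewer genes and gave 205 higher and 147 lower for Al in wild type, 241 and 122 for Al in wrky47, 3 and 6 for genotype in control solution, 11 and 3 for genotype in Al, and 5 and 2 for the difference of the responses. By their construction the 1.5-fold threshold gave more (929 and 1167, 1092 and 880, 116 and 236, 171 and 126, 257 and 107, in the same order) and the 3-fold threshold fewer (126 and 69, 147 and 74, 1 and 3, 3 and 0, 1 and 1). Without the filter, which adds genes near the floor, 41 genes were lower in wrky47 in control solution and 24 in Al, 52 and 28 differed in response, and r was 0.83 for the Al responses and 0.32 for the genotype differences. The offset, which shrinks differences of dim genes, gave 6 and 14 for genotype in control solution, 17 and 9 in Al, and 7 upward differences of the responses. Quantile normalization gave 10 and 11 for the difference of the responses, and centring and 75th-percentile scaling 9 and 12 each, where the cause was not tested. The remaining 55 of 100 counts stayed within 1.5 times and 14 of 16 correlations within 0.05. Centring, 75th-percentile scaling and the second table cannot change a correlation, and the second table cannot change a count. Signal over the floor limits the dim genes: 817 and 763 genes were detected in 1 solution only in wild type and wrky47. No paired analysis was possible because each group has 1 array, so that the groups share fewer than 2 replicate numbers. An additive fit of genotype and solution over the 4 arrays, which would take the difference of the responses as its error, was not run.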

Other observations

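The gene ontology terms named here come from the deposited annotation and were chosen after their values were seen, out of 683 terms with 10 to 200 genes. Genes annotated to the respiratory burst, the burst of reactive oxygen in defence, had a median Al response of 0.57 in wild type, with 85 of 101 above 0 and 29 higher by 2-fold, and 0.68 in wrky47, with 85 of 100 above 0 and 33 higher. Callose deposition, the sealing of walls with a glucan that is a known mark of Al injury, stood at 0.77 in wild type (13 of 40 higher) and 0.89 in wrky47 (12 of 41 higher). The cellular response to hypoxia had a median of 1.54 in wild type (11 of 16 higher) and 1.36 in wrky47 (9 of 16 higher). The unfolded protein response of the endoplasmic reticulum was at 0.34 (123 of 157 above 0) and 0.42 (131 of 159). The term for the cellular response to iron starvation was at -0.49 in wild type, where 19 of 104 genes were lower by 2-fold, and -0.45 in wrky47, where 23 of 103 were. The medians of the iron deficiency list fixed in advance did not share this direction, at 0.05 (percentile 93.2) in wild type and 0.23 (percentile 96.63) in wrky47. In wild type, however, the measured members of the list that passed 2-fold, NAS1 and NAS2, fell and its mean was below 0. The iron transporter IRT1 was lower there as a bound. Anaphase genes in wild type had a median of -0.48 with 3 of 79 above 0, and methionine synthesis genes were at -0.38 with 8 of 100 above 0.

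Between the genotypes, trichoblast differentiation in control solution had 22 of 23 genes below 0 in wrky47 (median -0.70). In Al, pyrimidine ribonucleotide synthesis had 102 of 119 genes above 0 in wrky47 (median 0.21) and protein import into the nucleus 78 of 86 (median 0.22). Nitrate transport had 45 of 189 above 0 (median -0.15), the iron starvation term 27 of 103 (median -0.14) and phosphatidylinositol synthesis 11 of 79 (median -0.13), while the iron deficiency list had 6 of 10 above 0 (median 0.04). In the difference of the responses, where the median of all genes was 0.05, ribosome biogenesis had 99 of 126 genes above 0 (median 0.14), cytokinesis 101 of 137 (median 0.18) and RNA methylation 143 of 186 (median 0.13). Relative to genes of like signal these medians were 0.11, 0.11 and 0.10. The genes of a term are not independent of each other, and these counts describe single arrays.

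The log2 signal of the 3′ probe set over the 5′ probe set had a range over the 4 arrays of 0.24 for actin, 0.25 for GAPDH, 0.08 for ubiquitin, 0.32 for the Dap spike-in and 0.35 for the Thr spike-in. The ribosomal 25S probe set, with a range of 0.63, had log2 signals of 12.26 in wild-type control, 12.56 in wrky47 control, 12.69 in wild-type Al and 12.88 in wrky47 Al, and the mean signals of the Thr spike-in were 5.91, 6.13, 6.39 and 6.32 in the same order.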
